A study of Homo sapiens with 2 samples.

How the data were processed

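Gene expression was measured in H1299 cells, an established human non-small cell lung cancer line, after transfection with a miR-138 mimic or a negative control (NC) mimic. A mimic is a synthetic RNA duplex that delivers a mature microRNA. Per the labels' protocols, cells in medium with 10% fetal bovine serum were transfected by lipofection at 70% confluence, total RNA was isolated with a phenol-based reagent, and amplified cDNA was biotin-labelled. The labels give 48 h of transfection and a whole-transcript Affymetrix human transcriptome array, which reports 1 value per transcript cluster (all probes assigned to 1 gene or transcript group). There was 1 array per mimic, and nothing in the labels describes further cultures.

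The deposited values are on a log2 scale with 2 decimals, 1 column per array. Per the submitters' processing notes, they were made with Affymetrix Expression Console. Its version, the summarisation, the normalization between arrays and any filter are not given in the sources used here. The log2 base was inferred from the deposited values: the highest, 14.07, stands for a signal of 17199 as a log2 value and 1289803 as a natural logarithm, and a 16-bit scanner records at most 65535. The table held 243 transcript clusters, and the smallest absolute difference between the 2 arrays was 1.00. The table is therefore a list limited to differences of at least 2-fold, not a whole array. A gene outside it was not analysed here, and neither the share of the array that differed nor an enrichment against all measured genes could be computed. Centring could be estimated only from these 243 features.

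Gene names came from the platform's annotation. Of the 243 transcript clusters, 221 had 1 gene, 9 had several and were not named, and 13 were unnamed here. Through gene identifiers, 215 names were matched to a current human gene table (assembly GRCh38.p14), and 6 more were matched by symbol or synonym. This updated 1 symbol, and 1 cluster with a pair of symbols carried an old and a current name of the same gene, AGO2. The feature IDs name no genome build, so no coordinates are given. The chromosome is the one coded in the feature ID. Probe sequences were not used here, so hybridisation shared between related genes, such as the zinc finger genes, the SAMD9 pair or POU5F1B and its parent gene, could not be separated.

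Each feature's log2 difference was computed as the miR-138 mimic minus the NC mimic. With 1 array per group there is no residual degree of freedom, so no test was made, no p-value is given and no error can be attached to a value. The 37 gene lists, the rule for naming genes and the alternative settings were fixed before the data were examined. Among features with 1 gene outside the lowest 25% of mean levels (log2 6.57), the 15 largest positive and 15 largest negative differences were named, with all members of a list of reported miR-138-5p targets and up to 4 members of each other list. Genes named outside this rule were chosen after their values were seen, as stated where they appear. For lists with at least 5 members in the table, the median difference was placed among 10000 random lists of the same size, drawn from the table and matched by quartile of mean level. This percentile describes these 2 arrays and does not measure replication.

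The percentile was tested on simulated data, with 20 simulated tables of 243 features and a list of 18. Its median was 40.1 with nothing added (range 8.7 to 95.1). It was at least 92.9 when all members were made higher, and 80.5 in the median when 2 was added to every member, with a lowest value of 60.5 that lies inside the range with nothing added. A first pass limit, a percentile above 95 in every simulated table with the added shift, was not met. It was lowered to 90 for lists with all members higher and dropped for the shift, so the percentile missed a shift of this size in some simulated tables. Adding 2 placed most of the lower members between -1 and 1, where the deposited table holds no feature. The shifted setting therefore differs from the data and does not show how often a shift would be missed here. Because every deposited difference lies beyond 1 in either direction, a list's median follows the share of members on each side, so the counts in each direction are given with it.

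The alternatives were centring each array on its median over the table, leaving out dim features, other fold limits, and counting only features with 1 gene. A planned search for miR-138-5p seed matches in 3' untranslated regions was not run because no transcript sequences were used here. A planned change of pseudocount did not apply to log2 values. Python 3.11.15, NumPy 2.4.6 and Matplotlib 3.10.9 were used.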

Results

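The transcriptome of H1299 cells was compared between 1 culture transfected with a miR-138 mimic and 1 transfected with an NC mimic, each profiled on 1 array at 48 h. The comparison asks which transcripts differ when miR-138 is supplied to these lung cancer cells. The deposited table listed 243 transcript clusters that differed by at least 2-fold. Their median log2 signal was 7.52 on the miR-138 array (range 3.03 to 14.07) and 7.58 on the NC array (range 3.0 to 12.67). As there was 1 array per mimic, no difference below could be set against replicate spread, and "higher" and "lower" describe these 2 arrays only.

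The transcript cluster of MIR138-1, a gene that encodes miR-138, was the brightest feature on the miR-138 array. Its log2 signal was 14.07 there and 6.13 on the NC array, a difference of 7.94 or 246-fold. The direction matched the labels of both arrays. Whether this feature's probes detected the transfected mimic itself or transcripts of the gene could not be settled from the table, so the value checks the labels and is not a measure of the gene's expression. The next difference in size was 2.95, for IFI44L.

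Of the 243 transcript clusters, 104 were higher and 139 were lower with the miR-138 mimic. Most differences were close to the limit of the table. The median was 1.23 on the log2 scale (2.34-fold) among the higher features and -1.24 (2.36-fold) among the lower ones. A difference of 2 or more (4-fold) was reached by 9 higher and 9 lower features. The higher features were more often dim: they made up 42.8% of the table, and 33.1% of the 121 features above the median level.

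**Figure D1:**
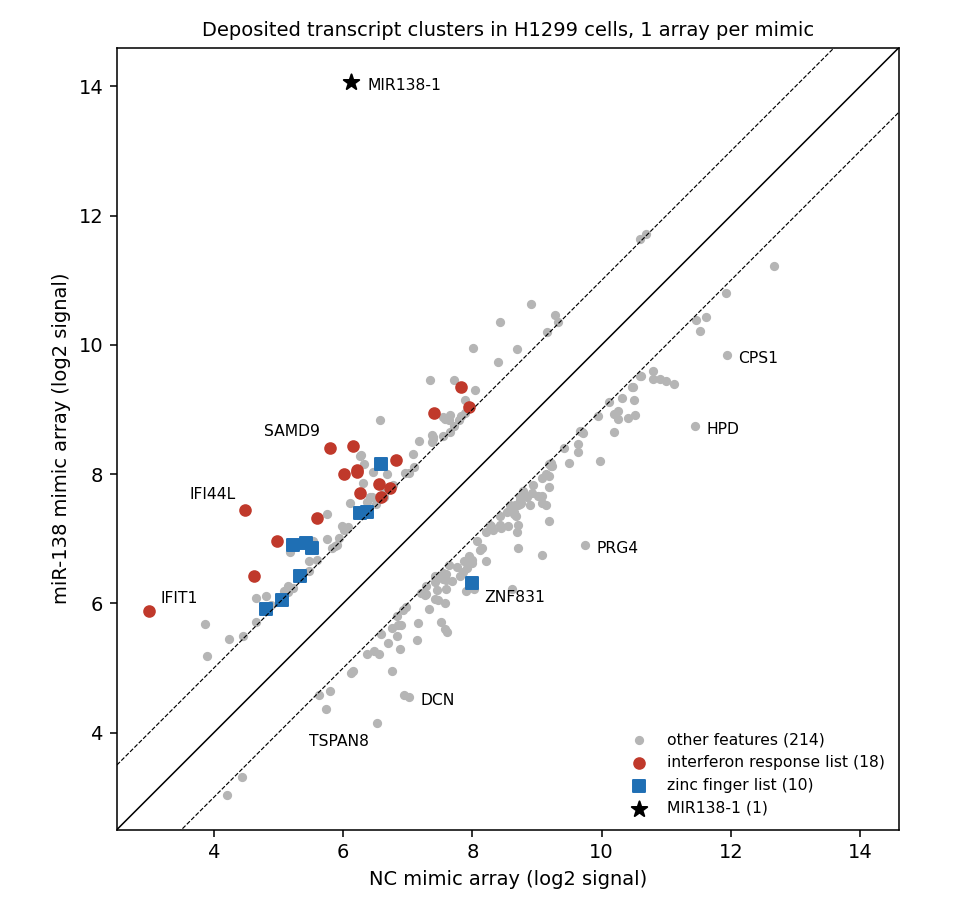
Log2 signal of the 243 deposited transcript clusters on the NC mimic array (x axis) and on the miR-138 mimic array (y axis), 1 point per feature. The solid line marks equal signal and the dashed lines a log2 difference of 1; MIR138-1 stands alone at 14.07 against 6.13, the 18 interferon response genes all lie above the upper dashed line, and 9 of the 10 zinc finger genes do.

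Interferon-response genes were the preset list with the most members in the table. Of its 80 symbols, 18 were in the table and all 18 were higher on the miR-138 array, with a median log2 difference of 1.77 and a range of 1.06 to 2.95. They included the cytoplasmic sensors of double-stranded RNA IFIH1 (8.43 against 6.15, a difference of 2.28) and RIGI (8.0 against 6.01, 1.99). The interferon-induced genes IFI44L, IFIT1 and SAMD9 differed by 2.95, 2.89 and 2.62, and IFIT3 by 1.85. HERC6, a HERC-family ligase, and UBE2L6, the enzyme that conjugates the ubiquitin-like protein ISG15, were higher by 1.82 and 1.53. ISG15 itself (1.54), the chemokine CCL5 (1.72) and OAS1 (1.06), which synthesises oligoadenylate in response to double-stranded RNA, were also among the 18 and are named here after their values were seen. The list's median lay at percentile 100 of random lists of the same size and levels, whose own median was -0.07, and none of the 10000 random lists had more than 16 members higher. IFIT1, at 3.0, was the dimmest feature on the NC array. Among the 13 members outside the lowest 25% of levels, 13 were higher, with a median of 1.53.

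The 2 listed NF-kB and cytokine genes were both higher: the cytokine IL6 by 2.01 (8.29 against 6.28) and the interleukin receptor IL7R by 1.05, the latter at a low level of 5.50. All 3 listed immediate early genes, which encode rapidly inducible transcription factors, were higher, namely EGR1 by 2.02, FOSL1 by 1.18 and JUN by 1.04. NR4A3, a gene of the same kind that was not on the list, was lower, at -1.13. It is named here after its value was seen. ANKRD1, a target of the coactivator YAP, was higher by 1.83, and with EGR1 made up the 2 members of the YAP and SRF target list, both higher. HMOX1, the heme-degrading enzyme, was higher by 1.93 (10.36 against 8.43), whereas ABCC2, the other member of the NRF2 target list, was lower, at -1.06. The arrestin-domain gene ARRDC3 was higher by 1.94. STC2, the single listed gene of the unfolded protein and ATF4 response, differed by 1.08, and the histone gene H2AC6 by 1.34.

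The p53 target list had 3 members in the table. The growth arrest genes GADD45A and GADD45B were higher by 2.11 and 1.02, and SESN3, a sestrin, was lower, at -1.80. H1299 cells themselves lack p53.

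Zinc finger transcription factor genes came next in number. Of 10 listed members, 9 were higher and 1 was lower, with a median of 1.12. ZNF461 (1.69), ZNF844 (1.57) and ZNF235 (1.51) had the largest positive differences, and all 9 higher members were coded to chromosome 19. The exception was ZNF831, coded to another chromosome, at -1.68. The chromosomes of zinc finger genes outside the table were not examined, so the shared chromosome is not a result of its own. The median lay at percentile 90.5 of matched random lists, and 134 of 10000 random lists had at least as many members higher. Most of these genes were dim: 4 of the 10 lay outside the lowest 25% of levels, and 3 of those 4 were higher. Probes shared between these related genes could not be separated.

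Genes of small RNA pathways and chromatin showed differences in both directions. AGO2, the Argonaute protein that carries microRNAs, was lower with the miR-138 mimic (7.28 against 9.19, -1.91). LIN28B, an RNA-binding protein that blocks let-7 maturation, was higher (8.04 against 6.46, 1.58). HDAC9, a histone deacetylase and the only listed chromatin modifier in the table, was higher by 1.74. Besides MIR138-1, the small RNA list held MIR4458, which was lower, at -1.03. Of 8 long non-coding RNA genes listed by symbol pattern, 4 were higher and 4 lower, with differences from -1.24 for PTPRG-AS1 to 1.24 for THUMPD3-AS1. The median of these 8, -0.02, lay at percentile 45.9 of matched random lists. DSCR9 (1.82) and GS1-600G8.3 (1.44), annotated as long non-coding RNA but missed by the pattern, were both higher. They are named after their values were seen, so the even split holds for the listed genes only.

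Among the named genes, PRG4, the secreted lubricant proteoglycan, had the largest negative difference (6.90 against 9.74, -2.84). HPD, a dioxygenase of tyrosine breakdown, differed by -2.70 and CPS1, the mitochondrial carbamoyl phosphate synthetase of the urea cycle, by -2.10. Both were bright on the NC array, at 11.44 and 11.94. MAP2K6, a kinase that activates p38, differed by -2.33. The phospholipid flippase ATP8B4 (-2.05), the methyltransferase TMT1A (-1.96), the water and glycerol channel AQP3 (-1.85) and the cytosolic phospholipase PLA2G4A (-1.81) followed. MTARC1, a mitochondrial reductase, differed by -1.77, the metalloreductase STEAP4 by -1.72, POU5F1B by -1.70 and the mechanosensitive channel PIEZO2 by -1.61. The list of solute carriers, channels and pumps had 4 members in the table, none of them a channel, and all were lower. They ranged from -1.54 for the fatty acid transporter SLC27A2, through ABCG2 at -1.29 and SLC43A3 at -1.12, to ABCC2 at -1.06. Among random lists of 4 named features, 11.71% had all members lower, so chance within this table could give this direction. FDPS, the one listed gene of sterol synthesis, differed by -1.19.

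All 3 listed mesenchymal genes were lower. These were the matrix proteoglycan DCN at -2.47 (4.55 against 7.02), the calcium-binding protein S100A4 at -1.61 and the matrix protein TGFBI at -1.0. Among random lists of 3 named features, 20.22% had all members lower, so chance within this table could give this direction. DCN was also the only member of the endothelial and fibroblast marker list in the table. Of 4 listed epithelial genes, 3 were lower, the junction proteins DSP (-1.14) and JUP (-1.09) and the trafficking protein MAL2 (-1.06). The tight junction gene OCLN was higher by 1.24. TSPAN8, a tetraspanin and the one gene of the integrin and adhesion list, differed by -2.37, at 4.15 on the miR-138 array.

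The list of reported miR-138-5p targets, compiled from general knowledge with 64 symbols including older names, had 1 member in the table. This was FOSL1, which was higher with the mimic (10.46 against 9.28). The other symbols of that list were not analysed here, and a difference under 2-fold in any of them could not be seen.

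Of the other lists, the ubiquitin ligase and protease list had 3 members higher and 3 lower, with a median of 0.05 at percentile 72.9. HERC6 and UBE2L6, both already counted on the interferon list, were its highest, and KLHL13 (-1.57) and TRIM29 (-1.48) its lowest. EXO1, the one listed replication gene, differed by -1.14, and the tumour antigen gene CTAG2 by -1.17. On the respiratory chain list, NDUFAF4 was higher by 1.12 and COX8C was lower, at -1.18, with COX8C near the bottom of the scale at 3.03. The remaining 13 of the 37 lists had no member among the named features and were not analysed here. They included mitosis, cyclins and their inhibitors, hypoxia, heat shock, receptor kinases, Wnt and related signalling, apoptosis, DNA repair, ribosomal proteins, membrane trafficking, immune cell markers and olfactory receptors. Each list was a fixed set of symbols or prefixes. An empty list therefore does not mean that the table held no gene of that process.

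**Figure D2:**
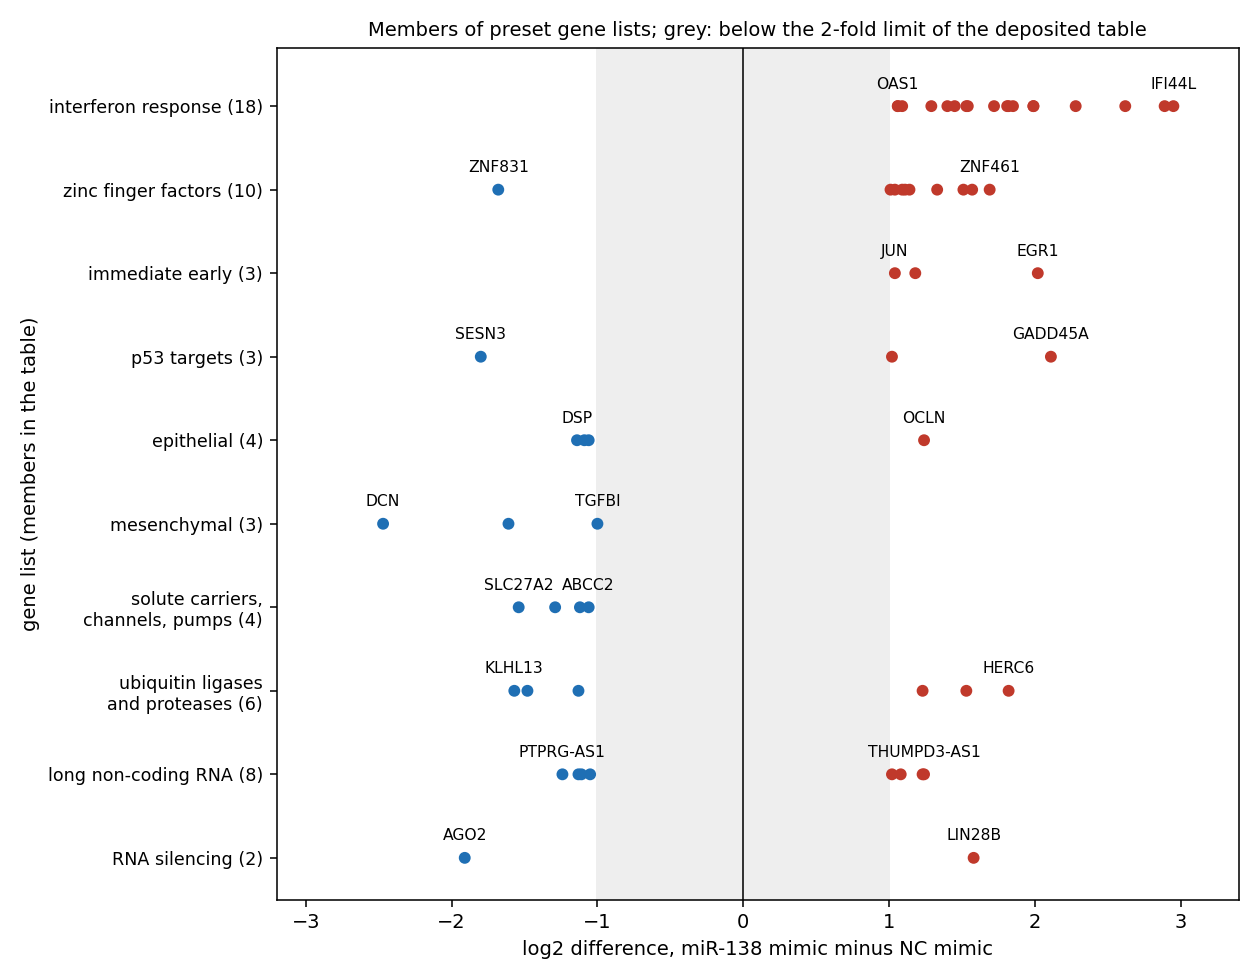
Log2 difference between the miR-138 mimic and the NC mimic array (x axis) for each member of 10 preset gene lists found in the table (rows, number of members in brackets), with the lowest and highest member named. Red points are higher and blue points lower with the miR-138 mimic. The grey band from -1 to 1 is empty because the deposited table holds only differences of at least 2-fold. All 18 interferon response genes lie to the right of the band. The 3 mesenchymal genes are all on the lower side, with TGFBI at the edge of the band, as are 139 of the 243 features in the table.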

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

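Counts followed the choice of features. Centring each array on its median over the table added 0.06 to every log2 difference. As the smallest difference was 1.0 in size, this could turn no gene's direction and says nothing about stability. Centring left 104 features higher by at least 1 and 121 lower, and gave 8.0 for MIR138-1. The higher count could not change, because features with differences just under 1 were not in the table. The median became 1.29 for the higher features, -1.18 for the lower features, 1.83 for the interferon response list, 1.19 for the zinc finger list and 0.11 for the ubiquitin list. The median of the long non-coding RNA list changed sign, from -0.02 to 0.05 with centring, where 4 members lie on each side, and to 0.06 outside the lowest 25% of levels, where 2 members were left, 1 on each side. Leaving out the lowest 25% of levels gave 69 higher features (113 lower), and medians of 1.53 for the interferon list and 1.09 for the zinc finger list. Above the median level 40 were higher and 81 lower. A log2 limit of 2 left 9 higher and 9 lower. A limit of 1.5-fold removed no feature and so tested nothing. Keeping only features with 1 gene gave 91 higher and 130 lower. Counting each gene once by its mean could not change these counts, because no gene had more than 1 such feature. No paired analysis was possible because there was 1 array per mimic, which also ruled out leaving out a replicate. Precision was limited by the number of arrays.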

Other observations

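All groups and tests in this part were chosen after the values were seen. Some groups that were not preset as such lay on the lower side, and 2 of them share members with the preset lists. All 4 cyclic-nucleotide phosphodiesterase genes in the table were lower with the miR-138 mimic, PDE8B at -1.38, PDE3A at -1.33, PDE4D at -1.16 and PDE7B at -1.14. The natriuretic peptide receptor genes NPR1 (-1.52) and NPR3 (-1.59) were lower as well. Of 6 genes for glutathione and peroxide enzymes and drug efflux pumps, 6 were lower, with ABCG2 and ABCC2 already counted on the solute carrier list. Among them were GSTT1 (-1.41), MGST2 (-1.35) and PRDX2 (-1.30). Of 5 genes of pyruvate and sugar phosphate metabolism, 5 were lower, including PDK4 (-1.80), a kinase that inhibits pyruvate dehydrogenase, and PDHA1 (-1.08), a subunit of that enzyme. Of 11 matrix proteins and matrix proteases, 11 were lower, with DCN and TGFBI already counted on the mesenchymal list and PRG4 already named. They included the aggrecan-cleaving protease ADAMTS5 (-1.34).

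Other groups were split. Among 7 amino acid and urea cycle enzymes, ASS1 (-1.45) and KYNU (-1.07) were lower with CPS1 and HPD, whereas BCAT1 (1.18), CDO1 (1.07) and ODC1 (1.03) were higher. Among 8 lipid genes, the elongases ELOVL4 (1.05) and ELOVL7 (1.10) were higher with FABP5 and UGT8, and SPTSSA (-1.29), SLC27A2, PLA2G4A and FDPS were lower. The related transcription factors ETS1 (1.27) and ETS2 (-1.53) lay on opposite sides. DDX60 (1.63) and SAMHD1 (1.20), both interferon-inducible, were higher although they were not on the interferon list. CFB, also interferon-inducible and off that list, was lower, at -1.32. These genes were picked by eye and do not show how such genes moved as a class. A group picked by eye from a table in which 139 of 243 features are lower gives no evidence of its own direction.

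The phosphodiesterase genes allowed a check of that point. One hypothesis is that cyclic-nucleotide breakdown was lowered as a group. Among 10000 random lists of 4 named features, 11.71% had all members lower, so chance within this table could give the same pattern, and the hypothesis is left without support from direction alone.

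The interferon-response pattern has 3 candidate explanations beside an effect of the miR-138 sequence itself. Noise of dim features, if independent between genes, would give mixed directions. No random list of the same size and levels had more than 16 of 18 members higher, against 18 observed. These lists treat related genes as independent draws, which they are not, so noise shared between the 18 genes is not excluded. An offset between the arrays as the whole cause would crowd unchanged features around the list's median of 1.77, yet 15 features lay within 0.2 of it and 69 between 1 and 1.4, a gap above 2 counting SDs (18.3). A smaller offset is not excluded. What also stays open is a difference between the mimic preparations or between the cultures, since interferon-inducible genes may respond together to transfected duplex RNA. With 1 transfection per mimic this cannot be told apart from an effect of the sequence.

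The chromosome 19 zinc finger features were 10 of 10 higher, with a median of 1.18. They count ZNF285 in 2 features, its own and 1 annotated to a pair of genes, and without the latter 9 of 9 were higher. Of the 7 other features coded to that chromosome, 4 were lower, HMG20B, CASP14, MFSD12 and PRDX2. That share is near the one in the whole table, 139 of 243. More copies of the whole chromosome 19 therefore stay open, because its genes that differed by less than 2-fold could not be seen. Noise of dim features stays open: 0.13% of random lists of the same size and levels had all members higher (0.21% for the 9 features), a value that treats related genes as independent draws, which they are not. Hybridisation shared between paralogs also stays open, because probe sequences would be needed. The span of their differences, 0.68, decides nothing here, since 69 of the 104 higher features lie between 1 and 1.4. A regulation of this gene family by miR-138 is a hypothesis that these 2 arrays do not test.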
